A study of Homo sapiens with 12 samples.

How the data were processed

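RNA sequencing of 12 libraries from MDA-MB-231 xenografts was analysed. MDA-MB-231 is an established triple-negative breast cancer cell line, and a xenograft is a tumour grown from it in a host animal. The libraries fall into 4 groups of 3 by their titles: PCDH, the control for the overexpression, and ADAR-OE, in which ADAR1 was overexpressed, each with CX5461 or with the treatment written as cmc-na. The series' design text describes tumours with or without CX-5461, so cmc-na is taken as the arm without that drug, and the abbreviation is not expanded here. Nothing in the labels says that the replicates of a group are separate animals, so all p-values measure the spread between these libraries, which may be in part technical.

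Per the labels' protocols, polyadenylated RNA was captured on beads, fragmented and copied into cDNA with random hexamers. Per the submitters' processing notes, fastp 0.23.4, STAR 2.7.11a, featureCounts 2.0.6 and the build hg38 were used; the role of each tool is not stated there. Whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical genes (PRSS2 and SPANXD among those named) are uncertain. Whether reads of the host were removed is not given in the sources used here either. The authors deposited a table of read counts per gene symbol, which is not normalized, with 61228 symbols. The authors also deposited a table of TPM values for 62700 Ensembl genes. The ratio of count to TPM was the same in all libraries apart from one factor per library: over 7849 genes with a unique symbol and more than 200 counts in every library, the largest deviation on the log scale was 6.38e-10, so both tables come from the same counts with one length per gene. Of the TPM symbols, 343 belong to more than 1 Ensembl gene; of these, 174 have counts, and the counts of all 174 are proportional to the TPM of 1 Ensembl gene. Of the count symbols, 20357 are Ensembl identifiers.

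Total counts ran from 11740052 to 16176090 per library. No library was a copy of another: the chi-square per degree of freedom between pairs of libraries ran from 4.77 to 58.2, and within groups from 4.77 to 47.6, where sampling noise alone gives about 1. The 11 pairs with ADAR-OE_cmc-na replicate 1 had 43.6 to 58.2, and the highest of all other pairs was 24.2.

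Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test) in one fit of all 12 libraries on the 4 group means, with no replicate block, over 16338 genes. A call is a Benjamini-Hochberg adjusted p under 0.05 over those genes. The comparisons fixed before the data were examined were CX5461 against cmc-na in PCDH and in ADAR-OE, ADAR-OE against PCDH without drug and with CX5461, and the interaction, which is the difference of the drug effects. The average of the drug effects and the average of the overexpression effects were added after the data had been seen. Comparisons that share a group are not independent. The ADAR-OE libraries without drug enter CX5461 in ADAR-OE and ADAR-OE without drug with opposite signs, and also the interaction. Unless another tool is named, adjusted p-values of genes come from this edgeR test, log2 fold changes are given ± SE, and levels are CPM (counts scaled to the TMM-adjusted library size) as mean ± SD with n = 3 per group. The common biological coefficient of variation was 0.134.

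There were 25 gene lists, fixed at the same time. They cover interferon-stimulated genes, antigen presentation by MHC class I, NF-kB and inflammatory cytokine genes, p53 targets, homologous recombination and DNA damage signalling, DNA replication and E2F targets, mitosis, RNA polymerase I and ribosome biogenesis, cytosolic ribosomal proteins, R-loop and G-quadruplex processing, RNA editing and double-stranded RNA sensing, the integrated stress and unfolded protein responses, hypoxia and glycolysis, sterol synthesis, mesenchymal and invasion genes, immediate early genes, replication-dependent histones and mitochondrially encoded genes. The other 7 hold markers of fibroblasts, endothelial cells, leukocytes, adipocytes, skeletal muscle, erythroid cells, and keratinocytes and luminal epithelium. Lists of at least 3 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 24 lists tested in a comparison. The same test with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, stand beside it. For each list the number of calls over all genes and the number adjusted over the list alone were counted.

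Genes were named by a rule fixed then too: ADAR everywhere; per comparison, among called genes with at least 5 CPM on average and no overlap between the groups compared (in both arms for the averages), the 8 with the largest change each way, passing over pseudogene-style symbols, non-coding families and unnamed identifiers; per list up to 3 called members, or else the most abundant 1; and 15 fixed genes, of which those the text speaks of are given. With 3 libraries against 3, chance leaves 10% of genes without overlap. Some genes that the rule names are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

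Each comparison was repeated with RLE and with upper-quartile factors, without the filter, with at least 1 CPM in 3 libraries, with DESeq2 1.42.0 and limma-voom, with limma on log2(TPM + 1) and log2(TPM + 0.1), with the replicate number as a block, on the comparison's own groups alone, and without each library in turn. DESeq2 was given the counts without filterByExpr, so its results differ from the edgeR test in both the tool and the filter. Chosen after the data had been seen, each library's loess trend (span 0.5) of counts on GC content and gene length was removed in a further fit, and the list tests were repeated without each library. GC content, length and positions come from GENCODE release 29 on GRCh38; 96.9% of the tested genes have a value. The steps were tested on simulated counts with the real means and library sizes and 200 changed genes. The changed genes were drawn from those with at least 5 CPM on average, so the shares called do not cover weaker genes. In the simulated comparison of ADAR-OE with PCDH without drug (16010 genes), 100% of 4-fold, 96% of 2-fold and 58% of 1.5-fold changes were called, with 4 false calls. In the simulated drug effect in PCDH (16007 genes) the shares were 100%, 92% and 54%, with 5 false calls. A simulated GC trend in the PCDH libraries without drug gave 279 false calls over 16338 genes, and 10 once the trend was removed. The simulated trend was steeper than the measured one (mean slope -0.0760 log2 per 10 points), so 279 does not estimate the false calls in the data. Of simulated lists, 5 of 5 raised lists and 0 of 15 unchanged lists were called. Each simulated gene varied on its own, without correlation within a list. In the data the estimated correlation within a list ran from -0.00715 (p53 targets) to 0.815 (mitochondrially encoded genes). The simulation therefore does not show that the preset correlation holds for the real lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.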

Results

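Poly(A) RNA was sequenced from xenografts of MDA-MB-231, a triple-negative breast cancer cell line. Of the 12 libraries, 3 were PCDH without drug (PCDH_cmc-na), 3 were PCDH with CX5461, 3 were ADAR-OE without drug (ADAR-OE_cmc-na) and 3 were ADAR-OE with CX5461. ADAR encodes ADAR1, an enzyme that changes adenosine to inosine in double-stranded RNA and keeps such RNA from setting off interferon responses. CX-5461 inhibits RNA polymerase I, which transcribes ribosomal RNA, and binds G-quadruplex DNA. The total counts of replicates 1 to 3 were 12703880, 13100990 and 15076981 in PCDH without drug, and 11740052, 12678412 and 14635702 in PCDH with CX5461. In ADAR-OE they were 14463207, 15781154 and 16176090 without drug, and 12321315, 14756484 and 14532694 with CX5461.

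The libraries differed in ways other than their labels. Genes rich in GC were counted low in all 3 libraries of PCDH without drug, whose slopes of log2 level per 10 points of GC content were -0.0592, -0.0979 and -0.0710. The group means ± SD of this slope were -0.0760 ± 0.0198 in PCDH without drug, 0.0154 ± 0.00962 in PCDH with CX5461, 0.0385 ± 0.0504 in ADAR-OE without drug and 0.0221 ± 0.0318 in ADAR-OE with CX5461. Mitochondrially encoded genes took 3.45% of the counts in ADAR-OE without drug replicate 1, and between 6.05% and 9.49% in the other 11 libraries. Long genes were counted low in the same replicate 1, with a slope of -0.117 log2 per doubling of gene length. In the other 11 libraries this slope ran from -0.0349 to 0.0804. The first principal component held 19.6% of the variance over the 2000 most variable genes, and PCDH without drug replicate 2 lay at -37.3 on it, against -11.5 to 17.4 for the others.

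**Figure D1:**
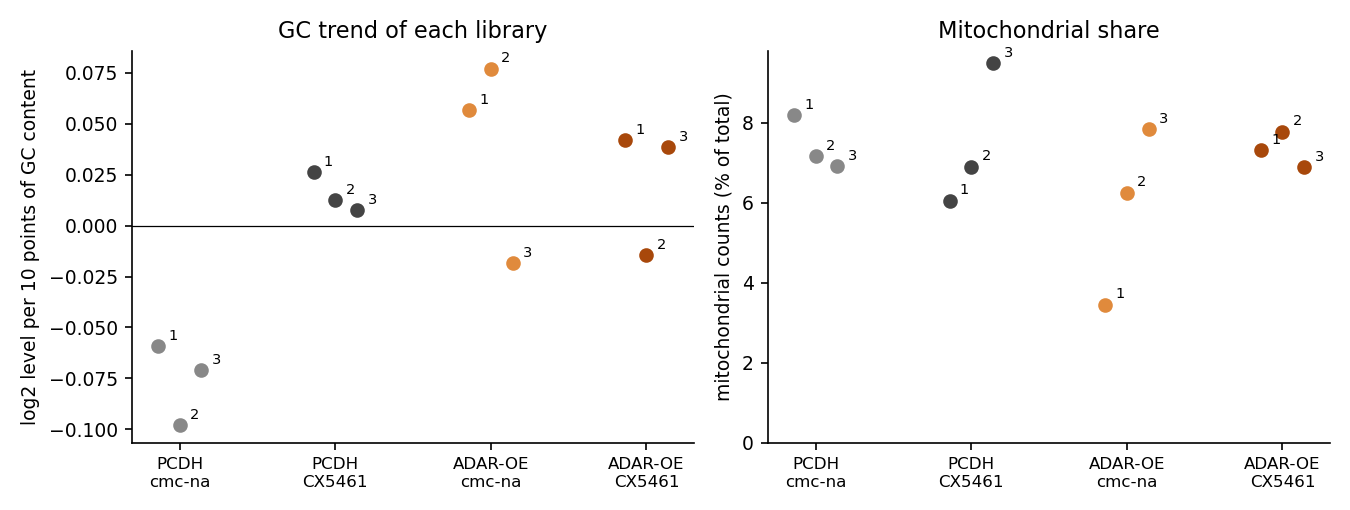
The left plot gives each library's slope of log2 level on GC content (log2 per 10 points) and the right plot its mitochondrial counts (% of total), by group, with the replicate number beside each point. The 3 PCDH libraries without drug have the lowest slopes, and ADAR-OE without drug replicate 1 has the lowest mitochondrial share, 3.45%.

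The first question was what ADAR1 overexpression changed in tumours without CX5461. ADAR (chromosome 1, 154582057 to 154628013, minus strand) stood at 187 ± 2.59 CPM in PCDH and 763 ± 118 in ADAR-OE (SD, n = 3 each), a log2 fold change of 2.03 ± 0.12 (adjusted p = 7.73e-08). BST2 (chromosome 19, 17402939 to 17405648), an interferon-stimulated membrane protein that tethers virus particles, rose from 34.7 ± 7.10 to 87.9 ± 9.42 CPM (log2 fold change 1.34 ± 0.15, adjusted p = 0.000356). DMD (chromosome X, 31097677 to 33339441), which encodes dystrophin, a link between the cytoskeleton and the matrix, fell from 35.9 ± 10.8 to 8.13 ± 2.60 CPM (log2 fold change -2.14 ± 0.21, adjusted p = 9.90e-05). FN1 (chromosome 2, 215360440 to 215436172), which encodes the matrix protein fibronectin, fell with a log2 fold change of -0.93 ± 0.20 (adjusted p = 0.0241).

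Of 16338 genes, 358 were called between ADAR-OE and PCDH without drug, 106 higher and 252 lower, and 63 of them changed more than 2-fold. Of the 358, 351 did not overlap between the groups, as did 19.9% of all tested genes, where chance gives 10%. Fitted on its own groups alone, the comparison gave 26 calls. It gave 238 with the replicate block, 931 with DESeq2 and 1054 without the filter. Upper-quartile factors gave 132 higher and 182 lower. On the TPM scale the balance was the other way, with 13 higher and 7 lower for log2(TPM + 1) and 8 higher and 3 lower for log2(TPM + 0.1). Among the called genes with at least 5 CPM on average and no overlap between the groups, the largest increases were in TNFRSF17, a receptor of B-cell survival factors (log2 fold change 2.16 ± 0.35), SPNS2, an exporter of sphingosine-1-phosphate (2.16 ± 0.23; chromosome 17, 4498838 to 4539035), and TRIML2, a TRIM-family protein (2.16 ± 0.22; chromosome 4, 188091273 to 188109603). PRSS2, a trypsinogen whose reads are shared with paralogs, rose by 1.93 ± 0.36 on the log2 scale, and KISS1, which encodes a secreted metastasis suppressor, by 1.17 ± 0.27. NOXA1, an activator of NADPH oxidase, rose by 1.09 ± 0.23 and SH2D3A, a signalling adaptor, by 1.05 ± 0.21. Among the decreases were the protocadherins PCDH1 (-2.19 ± 0.41) and PCDH7 (-1.49 ± 0.18), cell adhesion genes that share only letters with the group name. CD33, a sialic acid-binding receptor (-1.69 ± 0.27), TMPRSS15, a protease that activates trypsinogen (-1.67 ± 0.29), CRYBG3, a protein with crystallin-like domains (-1.36 ± 0.27), NF1, a brake on RAS (-1.33 ± 0.31), also fell, as did PTPRU, a receptor phosphatase. Of 1 called gene, a group had no counts in any library, so that its fitted fold depends on the prior count. Genes called higher had a median GC content of 59.0% and genes called lower 40.0%, against 47.9% over all tested genes; the lower ones had a median length of 7196.5 nt against 3253 nt. With each library's GC and length trends removed, 55 genes were called, 22 higher and 33 lower, of which 49 were among the 358. Leaving out 1 library moved the count to 766 (PCDH without drug replicate 1), 22 (replicate 2) and 76 (replicate 3), to 120 and 667 (ADAR-OE without drug replicates 1 and 2), to 221 (PCDH with CX5461 replicate 2), and to 229 and 238 (ADAR-OE with CX5461 replicates 1 and 3).

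Genes of antigen presentation by MHC class I were higher in ADAR-OE without drug as a list of 17 (median log2 fold change 0.29, camera adjusted p = 0.000437, adjusted p = 0.592 with an estimated correlation). Over all genes 1 member was called, and 7 members, all higher, passed adjusted over the list alone. Without PCDH_cmc-na replicate 1 the median was 0.13 and the camera adjusted p 0.0337. Mesenchymal and invasion genes were lower as a list of 24 (median -0.21, camera adjusted p = 0.0027, adjusted p = 0.592 with an estimated correlation). Its 3 called members were FN1, ZEB1, a repressor of epithelial genes (-0.68 ± 0.12), and THBS1, which encodes thrombospondin-1 (-0.74 ± 0.18), and 4 passed adjusted over the list alone. That list had a median of -0.11 and an adjusted p of 0.0761 without PCDH_cmc-na replicate 2. All 13 mitochondrially encoded genes were lower (median -0.46, camera adjusted p = 0.000437, adjusted p = 0.809 with an estimated correlation; 0 members passed either way). Without ADAR-OE_cmc-na replicate 1, the library with the low mitochondrial share, the median was -0.13 and the adjusted p 0.0909, and without replicate 3 of that group the median was -0.72. Of 8 fibroblast markers 7 were lower (median -0.70, camera adjusted p = 0.0121, adjusted p = 0.592 with an estimated correlation). The adjusted p was 0.0629 and 0.0716 without ADAR-OE_cmc-na replicates 2 and 3, and the median was -1.14 without replicate 1. Its 1 called member, also the 1 adjusted over the list alone, was DCN, which encodes the matrix proteoglycan decorin (-4.57 ± 0.77). DCN had 225 counts over the 12 libraries, and the list's tested members had a median level of 1.34 CPM. The sizes of their folds are therefore uncertain, in this and the other comparisons. The list of RNA polymerase I and ribosome biogenesis had a median of 0.11, a mean of 0.02 and a camera adjusted p of 0.942. POLR1F and POLR1B, subunits of RNA polymerase I, and UTP20, a factor of ribosomal RNA processing, were called lower (-0.60 ± 0.12, -0.44 ± 0.11 and -0.58 ± 0.12). In this list 5 members, all lower, passed adjusted over the list alone. LOX, a collagen cross-linking enzyme (-0.72 ± 0.14), CENPF, a kinetochore protein (-0.55 ± 0.13), and SAMD9, an interferon-induced antiviral gene (-0.95 ± 0.22), were also called lower, in lists that were not called. Of the interferon-stimulated genes, 14 were higher and 27 lower (median -0.13, camera adjusted p = 0.555).

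The same question was asked in the presence of CX5461. ADAR stood at 211 ± 9.08 CPM in PCDH and had a log2 fold change of 2.25 ± 0.12 in ADAR-OE (adjusted p = 1.62e-08). TNFRSF17 (2.54 ± 0.39), TRIML2 (1.86 ± 0.22), SPNS2 (1.57 ± 0.23) and BST2 (1.12 ± 0.16, adjusted p = 0.0026) rose again, and DMD (-1.31 ± 0.21, adjusted p = 0.0081), PCDH7 (-1.01 ± 0.18) and DCN (-4.98 ± 0.75) fell again. CALB2, which encodes the calcium-binding protein calretinin (chromosome 16, 71358713 to 71390438), rose from 14 ± 2.4 to 36.4 ± 1.5 CPM (1.37 ± 0.17, adjusted p = 0.0011). PSMB9, an immunoproteasome subunit that shapes peptides for MHC class I (chromosome 6, 32844136 to 32859585), rose from 14.2 ± 1.55 to 24.6 ± 2.53 CPM (0.79 ± 0.13, adjusted p = 0.0081).

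With CX5461, 28 genes were called, 19 higher and 9 lower, 24 of them more than 2-fold, and all 28 without overlap between the groups, against 15.4% of all tested genes and 10% by chance. UGT8, an enzyme of galactolipid synthesis (1.78 ± 0.23), SPANXD, a cancer-testis gene with near-identical paralogs (1.4 ± 0.19), and SPDEF, an epithelial transcription factor (1.02 ± 0.18), rose, and PTCH1, the Hedgehog receptor (-1.24 ± 0.18), fell. Without drug, UGT8 had 0.77 ± 0.21 (adjusted p = 0.0635) and PTCH1 -0.45 ± 0.19 (adjusted p = 0.194). No gene was called for the interaction, so none of these is shown to differ between the drug arms. The count was 14 and 15 without PCDH_CX5461 replicates 2 and 3, 44 without ADAR-OE_cmc-na replicate 1, and 12, 17 and 12 without ADAR-OE_CX5461 replicates 1, 2 and 3. Of 1 called gene, a group had no counts in any library.

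With CX5461, antigen presentation by MHC class I was the list with the smallest camera adjusted p (median 0.29, camera adjusted p = 3.70e-08, adjusted p = 0.393 with an estimated correlation). PSMB9 was called, with 8 members higher adjusted over the list alone. NF-kB and inflammatory cytokine genes (21 genes, median 0.34, camera adjusted p = 7.89e-06, adjusted p = 0.415 with an estimated correlation; 1 member, CCL2, named after its value was seen, adjusted over the list alone) were higher. Sterol synthesis genes (19 genes, median 0.16, camera adjusted p = 4.66e-05, adjusted p = 0.415 with an estimated correlation; 1 member, MSMO1, adjusted over the list alone) were higher. Interferon-stimulated genes (41 genes) had a median of 0.06 and a mean of 0.17 (camera adjusted p = 0.00229, adjusted p = 0.565 with an estimated correlation). BST2 was called and 2 members passed adjusted over the list alone. The adjusted p was 0.227 without PCDH_CX5461 replicate 3 and 0.414, with a median of -0.02, without ADAR-OE_CX5461 replicate 3. Mitosis genes were higher (28 genes, median 0.08, camera adjusted p = 0.00594, adjusted p = 0.711 with an estimated correlation; 0 members called either way). Without PCDH_CX5461 replicate 3 the adjusted p was 0.433. Hypoxia and glycolysis genes were lower (26 genes, median -0.10, camera adjusted p = 0.00976, adjusted p = 0.751 with an estimated correlation; 1 member, CA9, adjusted over the list alone). The adjusted p was 0.226 and 0.433 without PCDH_CX5461 replicates 2 and 3 and 0.0671 without ADAR-OE_CX5461 replicate 2. Immediate early genes were lower (18 genes, median -0.17, camera adjusted p = 0.00229, adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone, 1 member was higher and 4 lower, and the adjusted p was 0.405 without PCDH_CX5461 replicate 1. Markers of keratinocytes and luminal epithelium were higher (7 genes, median 0.19, camera adjusted p = 0.00496, adjusted p = 0.393 with an estimated correlation). KRT8, KRT18 and KRT14, named after their values were seen, were higher adjusted over the list alone. The adjusted p was 0.0721 without ADAR-OE_CX5461 replicate 3, where KRT14, a keratin of basal epithelium, had most of its counts.

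Other medians of these lists also moved by more than 1.5 times when 1 library was left out. The interferon median was 0.16 and 0.03 without PCDH_CX5461 replicates 1 and 3, and 0.11 without ADAR-OE_CX5461 replicate 1 or 2. The NF-kB median was 0.51 and 0.18 without ADAR-OE_CX5461 replicates 1 and 3. The sterol median was 0.10 and 0.25 without PCDH_CX5461 replicates 1 and 2, and 0.09 without ADAR-OE_CX5461 replicate 3. The mitosis median was 0.16 and 0.03 without PCDH_CX5461 replicates 1 and 3. The hypoxia median was -0.22, -0.03 and -0.04 without PCDH_CX5461 replicates 1, 2 and 3, and the immediate early median -0.01 without replicate 1 and -0.28 without replicate 2 or 3. The keratinocyte and luminal median was 0.09 without ADAR-OE_CX5461 replicate 3.

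**Figure D2:**
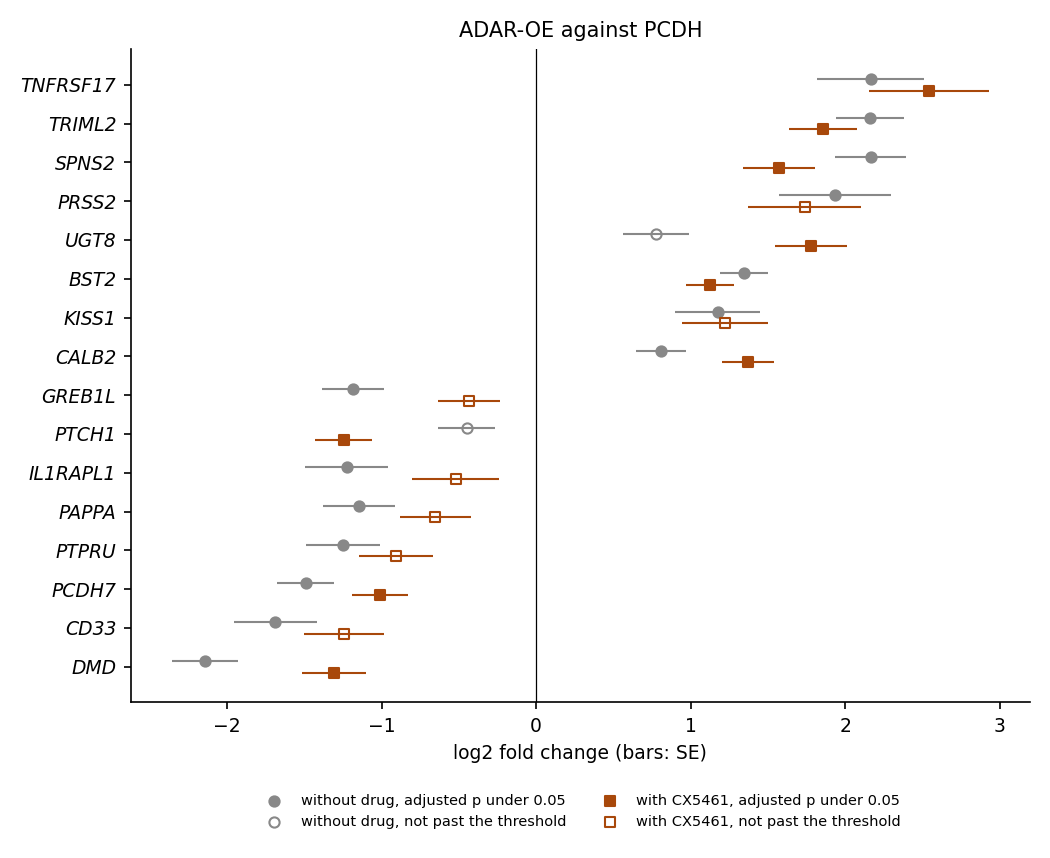
Each point is the log2 fold change of ADAR-OE over PCDH (bars, SE) of a gene, without drug in grey and with CX5461 in brown, filled where the adjusted p is under 0.05. All 16 genes have the same sign in both arms. They were chosen by a call on the average of the arms, which favours a shared sign, so this is no test of agreement.

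Over both drug arms, the overexpression effect was tested as an average, a comparison chosen after the data had been seen. ADAR had a log2 fold change of 2.14 ± 0.09 (adjusted p = 1.14e-10), and its interaction with the drug was 0.22 ± 0.17 (adjusted p = 0.751). TNFRSF17 (2.35 ± 0.26), TRIML2 (2.01 ± 0.16), SPNS2 (1.87 ± 0.16), PRSS2 (1.84 ± 0.26), UGT8 (1.28 ± 0.16), BST2 (1.23 ± 0.11), KISS1 (1.20 ± 0.20) and CALB2 (1.09 ± 0.12) rose. DMD (-1.73 ± 0.15), CD33 (-1.47 ± 0.19), PTPRU (-1.08 ± 0.17), PAPPA, a protease that frees insulin-like growth factors (-0.90 ± 0.16), IL1RAPL1, a synaptic adhesion gene (-0.87 ± 0.19), PTCH1 (-0.85 ± 0.13) and GREB1L, a developmental gene (-0.81 ± 0.14), fell, as did PCDH7. MX1, an interferon-induced GTPase against viruses, rose by 0.92 ± 0.18 on the log2 scale (adjusted p = 0.0157). The list of interferon-stimulated genes was not called (adjusted p = 0.534, 19 members higher and 22 lower), with a median of -0.03, a mean of 0.06 and an upward test.

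The average gave 351 calls, 139 higher and 212 lower, with 70 over 2-fold. Of these, 221 were free of overlap in both arms, as were 3.77% of all tested genes. Chance gives 10% in a single arm and far less in both together. Genes called lower had a median GC content of 41.6% and length of 6054.5 nt, and genes called higher 51.7% and 3257 nt. Over all tested genes the medians were 47.9% and 3253 nt. The GC and length trends may therefore take part in these calls. With the trends removed, 329 genes were called, 164 higher and 165 lower. That count alone does not say how many of the 351 were kept. On the TPM scale the balance was the other way, with 59 higher and 25 lower for log2(TPM + 1) and 56 higher and 23 lower for log2(TPM + 0.1). In 4 called genes a group had no counts. The count was 527, 188 and 225 without PCDH_cmc-na replicates 1, 2 and 3, 222 and 156 without PCDH_CX5461 replicates 1 and 2, and 166, 211 and 111 without ADAR-OE_CX5461 replicates 1, 2 and 3. The effects of the 2 arms had a Pearson r of 0.290 and a Spearman rho of 0.219 across 16338 genes, which are not independent replicates. Of the 358 genes called without drug, 312 (87.2%) had the same direction with CX5461, against 59.1% of all genes, and of the 28 called with CX5461, 27 (96.4%) had the same direction without drug. The arms shared 16 calls, 9 higher and 7 lower, where 0.123 and 0.139 were expected if the calls were independent. Among them, chosen after their values were seen, IDO1, which breaks down tryptophan and restrains T cells, had log2 fold changes of -4.62 ± 0.58 and -4.10 ± 0.53, and NUP210, a nuclear pore protein, 2.43 ± 0.38 and 3.11 ± 0.40. IDO1 averaged under 5 CPM over the 12 libraries, so the size of its fold is uncertain.

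On average over the arms, antigen presentation by MHC class I was higher (median 0.25, camera adjusted p = 9.84e-08, adjusted p = 0.405 with an estimated correlation, fry adjusted p = 0.0339). The 4 called members included PSMB9 (0.61 ± 0.09) and PSMB8, a further immunoproteasome subunit (0.35 ± 0.08), and 11 passed adjusted over the list alone. Fibroblast markers were lower (median -0.45, camera adjusted p = 0.0178, adjusted p = 0.405 with an estimated correlation, fry adjusted p = 0.0392). DCN was the 1 member called and the 1 adjusted over the list alone. The tested fibroblast markers had a median level of 1.34 CPM, so the size of their shift is uncertain. The MHC class I and fibroblast lists both kept their camera call without each of the 12 libraries in turn. Mesenchymal and invasion genes were lower (median -0.09, camera adjusted p = 0.0178, adjusted p = 0.487 with an estimated correlation). FN1 (-0.75 ± 0.14), ZEB1 (-0.42 ± 0.08) and THBS1 (-0.61 ± 0.12) were called, and 4 members passed adjusted over the list alone. Without PCDH_cmc-na replicate 2 the median was -0.04 and the adjusted p 0.0736, and without replicate 1 the median was -0.15. The other 7 lists called by camera lost that call without at least 1 library. NF-kB and inflammatory cytokine genes were higher (median 0.13, camera adjusted p = 0.0276, adjusted p = 0.812 with an estimated correlation). Sterol synthesis genes were higher (median 0.10, camera adjusted p = 0.0227, adjusted p = 0.783 with an estimated correlation). MSMO1, an enzyme of cholesterol synthesis, was called (0.36 ± 0.09). Keratinocyte and luminal markers were higher (median 0.27, camera adjusted p = 0.0276, adjusted p = 0.405 with an estimated correlation). R-loop and G-quadruplex processing genes were lower (median -0.10, camera adjusted p = 0.0349, adjusted p = 0.627 with an estimated correlation; 0.555 with GC and length trends removed). Hypoxia and glycolysis genes were lower (median -0.10, camera adjusted p = 0.0239, adjusted p = 0.812 with an estimated correlation). LOX (-0.50 ± 0.10) and CA9, a carbonic anhydrase (-1.15 ± 0.25), were called. Immediate early genes were lower (median -0.13, camera adjusted p = 0.0214, adjusted p = 0.627 with an estimated correlation). KLF6 was called (-0.35 ± 0.08). Mitochondrially encoded genes were lower (median -0.22, camera adjusted p = 0.0349, adjusted p = 0.837 with an estimated correlation). POLR1F (-0.49 ± 0.08) and UTP20 (-0.41 ± 0.09) were called lower.

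The adjusted p-values of those 7 lists without single libraries were as follows. The NF-kB list had 0.451 and 0.0715 without PCDH_cmc-na replicates 1 and 2, 0.194 and 0.316 without PCDH_CX5461 replicates 2 and 3, 0.77 without ADAR-OE_cmc-na replicate 2, and 0.119 and 0.425 without ADAR-OE_CX5461 replicates 2 and 3. The sterol list had 0.13 without PCDH_CX5461 replicate 1, and 0.0789 and 0.0912 without ADAR-OE_CX5461 replicates 2 and 3. The keratinocyte and luminal list had 0.0501 without PCDH_cmc-na replicate 1, 0.0589 without PCDH_CX5461 replicate 3 and 0.095 without ADAR-OE_CX5461 replicate 3. The R-loop list had 0.0961 without PCDH_cmc-na replicate 3, 0.13 without PCDH_CX5461 replicate 1, 0.0725 without ADAR-OE_cmc-na replicate 2 and 0.125 without ADAR-OE_CX5461 replicate 3. The hypoxia list had 0.265 without PCDH_cmc-na replicate 2, 0.0982 and 0.208 without PCDH_CX5461 replicates 2 and 3, 0.121 without ADAR-OE_cmc-na replicate 3 and 0.0553 without ADAR-OE_CX5461 replicate 2. The immediate early list had 0.13 without PCDH_CX5461 replicate 1 and 0.102 without ADAR-OE_cmc-na replicate 3. The mitochondrial list had 0.19 and 0.0579 without PCDH_cmc-na replicates 1 and 2, 0.388 without PCDH_CX5461 replicate 3, 0.614 without ADAR-OE_cmc-na replicate 1 and 0.0912 without ADAR-OE_CX5461 replicate 3. Among the medians, that of NF-kB was 0.09 without PCDH_cmc-na replicate 1 or ADAR-OE_CX5461 replicate 3, 0.08 without PCDH_CX5461 replicate 3, 0.03 without ADAR-OE_cmc-na replicate 2 and 0.23 without ADAR-OE_CX5461 replicate 1. The hypoxia median was -0.15 without PCDH_cmc-na replicate 1 or ADAR-OE_cmc-na replicate 2, -0.04 without PCDH_cmc-na replicate 2 and -0.16 without PCDH_CX5461 replicate 1. The sterol median was 0.05 and 0.16 without PCDH_CX5461 replicates 1 and 2, and 0.15 and 0.06 without ADAR-OE_CX5461 replicates 1 and 2. The immediate early median was -0.20 without PCDH_CX5461 replicate 2 and -0.22 without ADAR-OE_cmc-na replicate 2. The mitochondrial median was -0.14 without PCDH_cmc-na replicate 1 and -0.10 without PCDH_CX5461 replicate 3 or ADAR-OE_cmc-na replicate 1, and the keratinocyte and luminal median was 0.13 without ADAR-OE_CX5461 replicate 3.

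**Figure D3:**
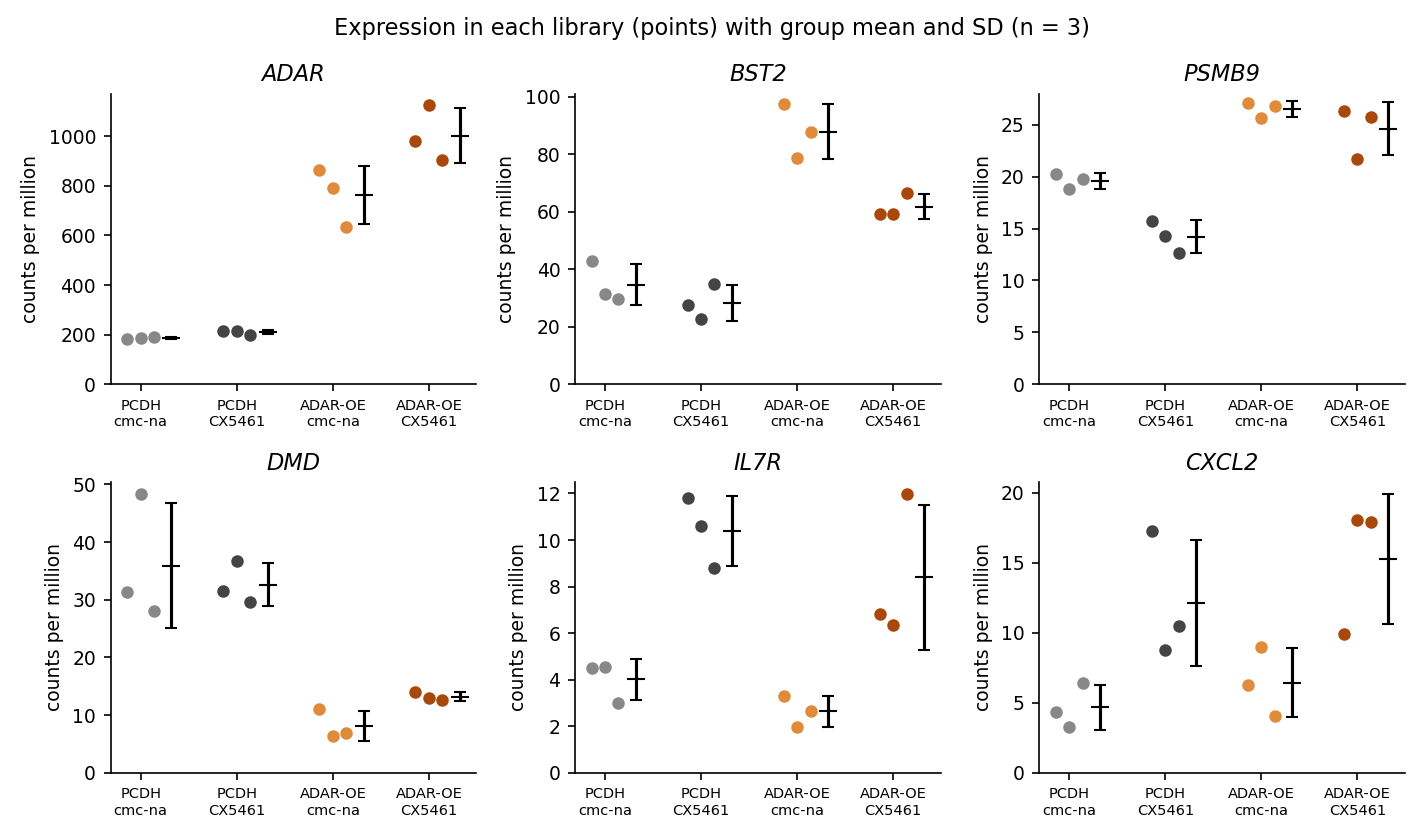
CPM in each library (points) with the group mean and SD (n = 3) for ADAR, BST2, PSMB9, DMD, IL7R and CXCL2 in the 4 groups. ADAR and BST2 are higher and DMD is lower in every ADAR-OE library than in every PCDH library of the same drug arm.

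The next question was what CX5461 changed in PCDH tumours. IL7R, the receptor of interleukin-7, had 4.01 ± 0.88 CPM without drug and 10.4 ± 1.51 with CX5461 (log2 fold change 1.38 ± 0.27, adjusted p = 0.0867). ALS2CL, a regulator of small GTPases (0.95 ± 0.18), and ADAMTSL4, a matrix protein (0.89 ± 0.17), had the same adjusted p, as did RESF1, a factor of retroelement silencing (-0.72 ± 0.14), STK38L, a kinase of the Hippo pathway (-0.59 ± 0.11), and RANBP2, a nuclear pore protein named after its value was seen (-0.69 ± 0.11). TOP2B, a topoisomerase that CX-5461 has been linked to, had -0.46 ± 0.10 (adjusted p = 0.0913). The GC content was 37.8% in RESF1, 35.5% in STK38L and 39.7% in TOP2B, and 59.0% in ALS2CL, 62.9% in ADAMTSL4 and 41.2% in IL7R. The PCDH libraries without drug counted GC-rich genes low, so that trend may take part in these values, though not in the rise of IL7R. Among the genes of the polymerase that the drug inhibits, POLR1A had 0.23 ± 0.10 (adjusted p = 0.326) and POLR1B 0.08 ± 0.11 (adjusted p = 0.796), and CDKN1A, a p53 target that stops the cell cycle, had 0.03 ± 0.15 (adjusted p = 0.953).

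No gene passed the edgeR test for CX5461 in PCDH; 2162 genes had an unadjusted p under 0.05, where 816.9 are expected by chance. DESeq2, run without the edgeR filter, called 273 genes and limma-voom, run with it, 0. Without the filter edgeR called 479. Without PCDH_cmc-na replicate 1 edgeR called 268 genes, 31 higher and 237 lower, and without ADAR-OE_cmc-na replicate 1 it called 41. Cytosolic ribosomal protein genes, which encode the proteins of the ribosome, were lower in 69 of 74 members (median -0.17, camera adjusted p = 7.68e-08, adjusted p = 0.988 with an estimated correlation; 0 members adjusted over the list alone), and kept the camera call without each library in turn. Immediate early genes, which respond to growth signals within minutes, were higher (median 0.40, camera adjusted p = 0.000861, adjusted p = 0.988 with an estimated correlation). The 5 members adjusted over the list alone included EGR1, a transcription factor (1.01 ± 0.34), DUSP1, a phosphatase of MAP kinases (0.62 ± 0.16), both named after their values were seen, and KLF6, a transcription factor (0.42 ± 0.11). Without PCDH_CX5461 replicate 1 the median was 0.07 and the adjusted p 0.115. NF-kB and inflammatory cytokine genes were higher (median 0.19, camera adjusted p = 0.00886, adjusted p = 0.988 with an estimated correlation). CXCL2, a chemokine for neutrophils, passed adjusted over the list alone (1.36 ± 0.33). The adjusted p was 0.545 without PCDH_cmc-na replicate 1 and 0.312 without PCDH_CX5461 replicate 1, with medians of 0.10 and 0.09, and the median was 0.43 without PCDH_cmc-na replicate 3. No member of the 3 lists was called over all genes. Interferon-stimulated genes were not called (adjusted p = 0.76), with a median of -0.02, a mean of 0.11 and an upward test, although 5 members passed adjusted over the list alone.

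The same was asked in ADAR-OE tumours. Without reaching the threshold, IL7R had a log2 fold change of 1.67 ± 0.28 (adjusted p = 0.203), OASL, an interferon-induced antiviral gene, of 1.46 ± 0.31 (adjusted p = 0.328) and IFIT1, an interferon-induced sensor of viral RNA, of 0.84 ± 0.19 (adjusted p = 0.328). The inflammatory cytokines IL1B (1.98 ± 0.43), IL6 (1.91 ± 0.40), CXCL1 (1.31 ± 0.29) and CXCL8 (1.14 ± 0.31), named after their values were seen, had adjusted p-values between 0.328 and 0.406. In PCDH, IL1B had 0.49 ± 0.41 and CXCL8 0.18 ± 0.31, and the interaction was 1.49 ± 0.59 for IL1B (adjusted p = 0.613) and 0.96 ± 0.44 for CXCL8 (adjusted p = 0.638). POLR1B had 0.47 ± 0.11 (adjusted p = 0.328), POLR1A 0.24 ± 0.10 (adjusted p = 0.488), CDKN1A 0.40 ± 0.15 (adjusted p = 0.461) and MYC, a growth-promoting transcription factor, 0.54 ± 0.15 (adjusted p = 0.406).

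No gene passed the edgeR test for CX5461 in ADAR-OE; 1583 had an unadjusted p under 0.05. DESeq2 called 18 and limma-voom 0. Without ADAR-OE_cmc-na replicate 2 edgeR called 117 genes, 94 higher and 23 lower. NF-kB and inflammatory cytokine genes were higher in 20 of 21 members (median 0.46, mean 0.76, camera adjusted p = 1.08e-12, adjusted p = 0.601 with an estimated correlation), with 8 higher adjusted over the list alone; its median was 0.85 without ADAR-OE_cmc-na replicate 2 and 0.72 without ADAR-OE_CX5461 replicate 1. Interferon-stimulated genes were higher in 31 of 41 (median 0.27, camera adjusted p = 5.77e-07, adjusted p = 0.601 with an estimated correlation), with 10 higher and 1 lower adjusted over the list alone. All 13 mitochondrially encoded genes were higher (median 0.58, camera adjusted p = 3.57e-07, adjusted p = 0.601 with an estimated correlation), with 3 adjusted over the list alone; without ADAR-OE_cmc-na replicate 1 the median was 0.15 and the camera adjusted p 0.00323. Cytosolic ribosomal protein genes were lower in 67 of 74 (median -0.17, camera adjusted p = 1.18e-07, adjusted p = 0.723 with an estimated correlation; 0 adjusted over the list alone). Without ADAR-OE_cmc-na replicate 1 the median was -0.000306 and the adjusted p 0.763, and without replicate 2 of that group the median was -0.27. Sterol synthesis genes (median 0.16, camera adjusted p = 0.000456, adjusted p = 0.601 with an estimated correlation; 3 adjusted over the list alone) were higher, with medians of 0.25 and 0.08 without ADAR-OE_CX5461 replicates 1 and 2. Mitosis genes (median 0.11, camera adjusted p = 0.000811, adjusted p = 0.666 with an estimated correlation; 0 adjusted over the list alone) were higher, as were mesenchymal and invasion genes (median 0.17, camera adjusted p = 0.00112, adjusted p = 0.601 with an estimated correlation; 1 adjusted over the list alone). Immediate early genes were higher (median 0.22, camera adjusted p = 0.00878, adjusted p = 0.601 with an estimated correlation; 4 adjusted over the list alone). Without ADAR-OE_cmc-na replicate 3 the adjusted p was 0.286. No member of these 8 lists was called over all genes. The ADAR-OE libraries without drug enter the overexpression comparison without drug with the opposite sign. A shift of that group alone would show in both. In ADAR-OE against PCDH without drug the medians were -0.46 for mitochondrial, -0.21 for mesenchymal, -0.13 for interferon, -0.10 for mitosis and -0.09 for immediate early genes. They were 0.01 for NF-kB, 0.02 for sterol and 0.01 for ribosomal protein genes.

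Averaged over PCDH and ADAR-OE, a comparison chosen after the data had been seen, CX5461 raised IL7R (chromosome 5, 35852695 to 35879603; 1.52 ± 0.19, adjusted p = 0.00639), CXCL2 (1.31 ± 0.23), OASL (1.24 ± 0.22) and IFIT1 (0.76 ± 0.13), the last 3 each with an adjusted p of 0.0409. ALS2CL (0.86 ± 0.13), ADAMTSL4 (0.69 ± 0.12), PLK2, a stress-responsive kinase (0.62 ± 0.11), and AMOTL2, a regulator of Hippo signalling (0.45 ± 0.08), also rose. RGCC, a regulator of the cell cycle (-0.68 ± 0.13), RESF1 (-0.55 ± 0.10) and STK38L (-0.47 ± 0.08) fell. Genes called lower had a median GC content of 38.5% and length of 5649 nt, and genes called higher 49.3% and 4420 nt. Over all tested genes the medians were 47.9% and 3253 nt. The baseline holds the PCDH libraries without drug, which counted GC-rich genes low, so that trend may take part in the lower calls. POLR1A had 0.23 ± 0.07 (adjusted p = 0.149), MYC 0.39 ± 0.10 (adjusted p = 0.129) and TOP2B -0.32 ± 0.07 (adjusted p = 0.0778).

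This average gave 18 calls, 12 higher and 6 lower. Of these, 15 were free of overlap in both arms, as were 2.72% of all tested genes, where chance gives 10% in a single arm and far less in both together. DESeq2 called 346, with the balance the other way (131 higher and 215 lower), and limma-voom called 2, both higher. Without the filter 269 were higher and 300 lower. On both TPM scales 0 genes were called, and with the replicate number as a block 1 was. Of all tested genes 2451 had an unadjusted p under 0.05. Without PCDH_cmc-na replicate 1 the count was 109, 20 higher and 89 lower, and without ADAR-OE_cmc-na replicate 1 it was 23, 10 higher and 13 lower. It was 4 and 2 without PCDH_cmc-na replicates 2 and 3, 5 and 1 without PCDH_CX5461 replicates 1 and 2, 401 and 1 without ADAR-OE_cmc-na replicates 2 and 3, and 1 and 2 without ADAR-OE_CX5461 replicates 2 and 3. Across 16338 genes, which are not independent replicates, the drug effects in PCDH and ADAR-OE had a Pearson r of 0.144 and a Spearman rho of 0.152, and 56.4% of genes had the same direction. NF-kB and inflammatory cytokine genes were higher (median 0.40, camera adjusted p = 2.27e-10, adjusted p = 0.548 with an estimated correlation; 1 called, 9 adjusted over the list alone). Immediate early genes (median 0.34, camera adjusted p = 9.40e-05, adjusted p = 0.548 with an estimated correlation; 0 called, 7 higher and 1 lower adjusted over the list alone) were higher. Interferon-stimulated genes were higher (median 0.09, mean 0.21, camera adjusted p = 0.00197, adjusted p = 0.889 with an estimated correlation; 2 called, 12 higher and 2 lower adjusted over the list alone). Cytosolic ribosomal protein genes were lower in 71 of 74 (median -0.18, camera adjusted p = 2.43e-12, adjusted p = 0.889 with an estimated correlation; 0 called either way). These 4 kept the camera call without each library in turn, but their medians moved by more than 1.5 times. Without PCDH_CX5461 replicate 1 they were 0.25 for NF-kB, 0.20 for immediate early and 0.05 for interferon-stimulated genes. Without ADAR-OE_cmc-na replicate 1 they were -0.10 for ribosomal protein and 0.04 for interferon-stimulated genes. The interferon median was also 0.14 without ADAR-OE_cmc-na replicate 2 or ADAR-OE_CX5461 replicate 2, and 0.04 without ADAR-OE_CX5461 replicate 3. Sterol synthesis genes (median 0.10, camera adjusted p = 0.016, adjusted p = 0.889 with an estimated correlation) and mitochondrially encoded genes (median 0.31, camera adjusted p = 0.014, adjusted p = 0.889 with an estimated correlation) did not. The sterol list had an adjusted p of 0.273 without PCDH_CX5461 replicate 2, 0.0511 without ADAR-OE_cmc-na replicate 3, and 0.132 and 0.0792 without ADAR-OE_CX5461 replicates 2 and 3, with a median of 0.04 in the first and 0.05 in the last 2 of these. The mitochondrial list had 0.0625 without PCDH_cmc-na replicate 3, 0.17 without PCDH_CX5461 replicate 3 and 0.301 without ADAR-OE_cmc-na replicate 1, with medians of 0.15 and 0.08 in the last 2.

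**Figure D4:**
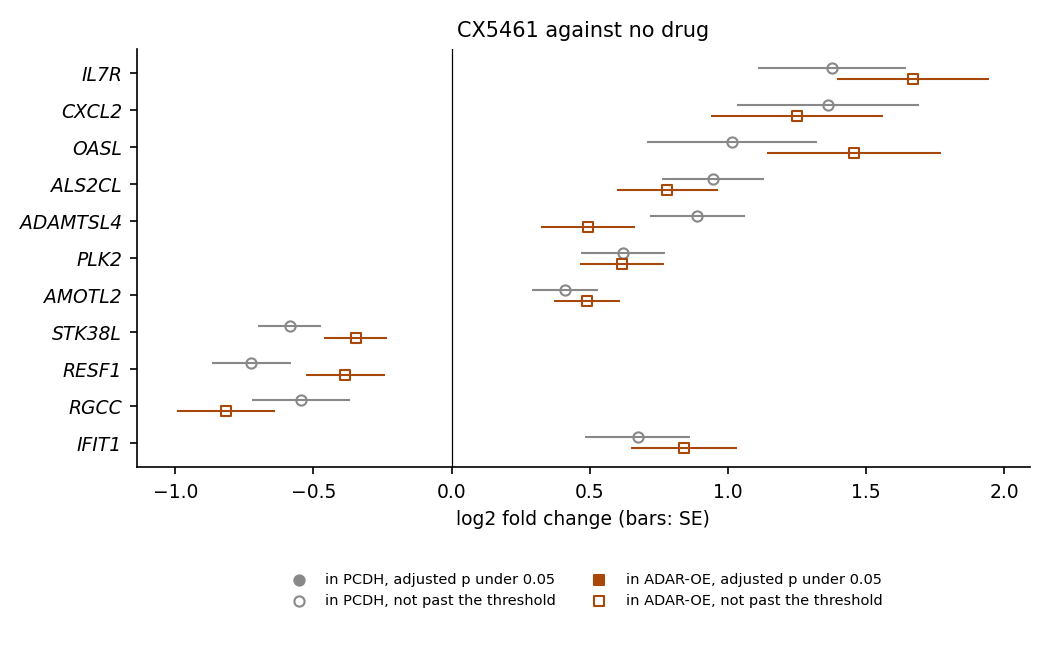
Each point is the log2 fold change of CX5461 over no drug (bars, SE) of a gene, in PCDH in grey and in ADAR-OE in brown; no gene passed the threshold in either alone. All 11 genes have the same sign in both. They were chosen by a call on the average of both, which favours a shared sign, so this is no test of agreement.

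Whether the drug effect differed between ADAR-OE and PCDH was asked by the interaction. IL1B (1.49 ± 0.59) had an adjusted p of 0.613 and IL7R (0.29 ± 0.38) of 0.87. No gene passed the edgeR test; 1256 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. By camera, 5 lists were higher: mitochondrially encoded genes, mitosis genes, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, and mesenchymal and invasion genes, with medians of 0.59, 0.20, 0.17, 0.27 and 0.16, and none had an adjusted p under 0.972 with an estimated correlation. No member of the 5 passed over all genes or adjusted over the list alone. The ADAR-OE libraries without drug enter the interaction too, so a shift of that group alone would also show here.

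**Figure D5:**
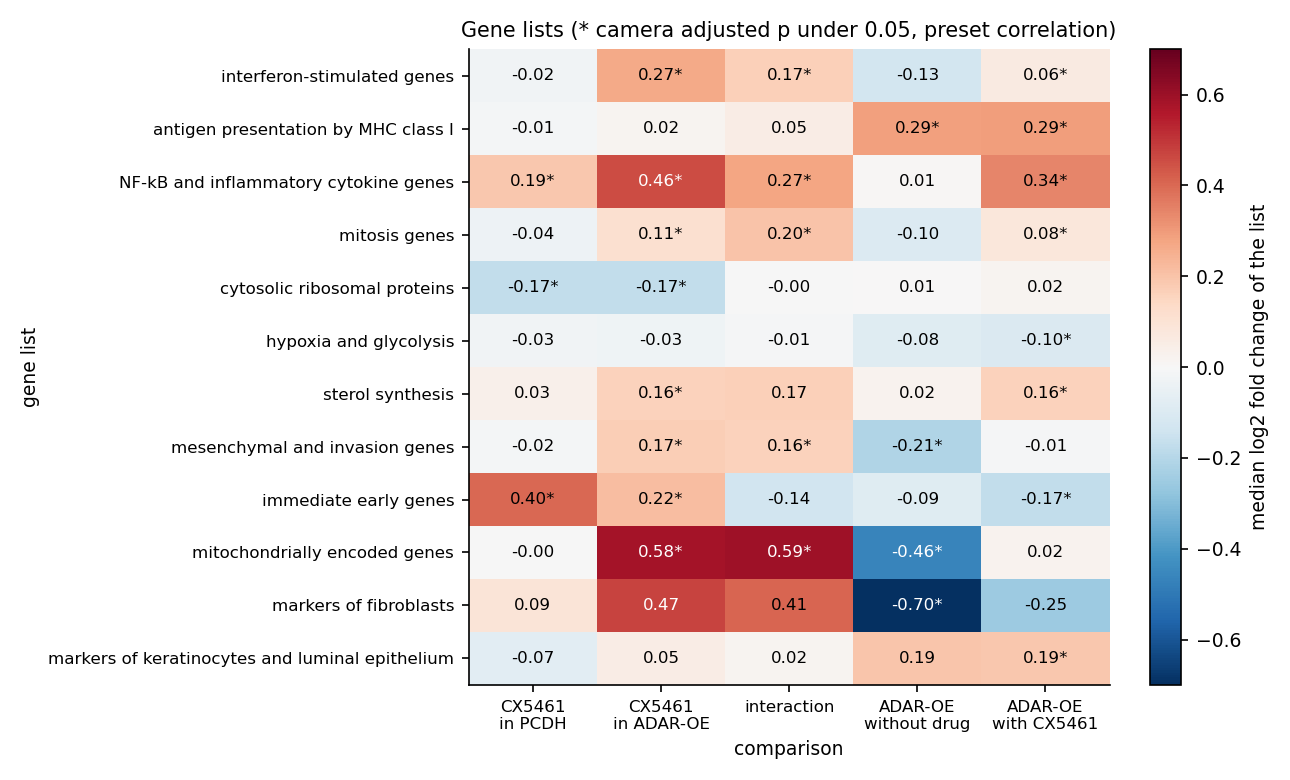
Each cell is the median log2 fold change of a gene list (vertical axis) in a comparison (horizontal axis), with an asterisk where the camera adjusted p with the preset correlation is under 0.05. The NF-kB list has its highest median, 0.46, for CX5461 in ADAR-OE, and the MHC class I list has 0.29 in both overexpression comparisons.

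In no comparison did camera call the lists of p53 targets, homologous recombination and DNA damage signalling, DNA replication and E2F targets, RNA polymerase I and ribosome biogenesis, RNA editing and double-stranded RNA sensing, the integrated stress and unfolded protein responses, histones, or the markers of endothelial cells, leukocytes, adipocytes and skeletal muscle. For CX5461 on average, the list of RNA polymerase I and ribosome biogenesis had a median of 0.03 (adjusted p = 0.157), RNA editing and double-stranded RNA sensing 0.09 (adjusted p = 0.157), p53 targets 0.01 (adjusted p = 0.919), and homologous recombination and DNA damage signalling -0.03 (adjusted p = 0.467). DNA replication and E2F targets had 0.03 (adjusted p = 0.467), the stress responses -0.08 (adjusted p = 0.207) and histones 0.16 (adjusted p = 0.207). Endothelial markers had 0.01 (adjusted p = 0.919), leukocyte markers 0.37 (adjusted p = 0.77), adipocyte markers -0.11 with a mean of 0.00 (adjusted p = 0.919) and skeletal muscle markers 1.75 (adjusted p = 0.467). For ADAR-OE on average, RNA editing and double-stranded RNA sensing had 0.08 (adjusted p = 0.109); ADARB1, the gene of the related editing enzyme ADAR2, had 0.06 ± 0.11 and DHX9, a helicase of double-stranded RNA, -0.13 ± 0.06 (adjusted p = 0.274). Of the erythroid list 0 genes had enough counts to be tested.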

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

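The removal of GC and length trends, the repeats of the list tests without each library, and the tests of PCDH_cmc-na replicate 2 alone and ADAR-OE_cmc-na replicate 1 alone were chosen only after the results were seen.

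The effect of CX5461 differed between ADAR-OE and PCDH for 5 gene lists by camera with its preset correlation. The median interaction log2 fold change was 0.17 for interferon-stimulated genes (adjusted p = 0.00573), 0.27 for NF-kB and inflammatory cytokine genes (adjusted p = 0.00706), 0.20 for mitosis genes (adjusted p = 0.000594), 0.16 for mesenchymal and invasion genes (adjusted p = 0.0222) and 0.59 for mitochondrially encoded genes (adjusted p = 4.44e-05). All 5 had an adjusted p of 0.972 with an estimated correlation. The mitosis and mitochondrial lists kept the camera call without each of the 12 libraries in turn, but without ADAR-OE_cmc-na replicate 1 the mitochondrial median was 0.30 (adjusted p = 0.00556). The interferon list had an adjusted p of 0.0998 without PCDH_CX5461 replicate 3, 0.0745 without ADAR-OE_cmc-na replicate 1 and 0.458 without ADAR-OE_CX5461 replicate 3. The NF-kB list had 0.153, 0.0544, 0.151 and 0.263 without PCDH_cmc-na, PCDH_CX5461, ADAR-OE_cmc-na and ADAR-OE_CX5461 replicate 3. The mesenchymal list had 0.277 without PCDH_cmc-na replicate 2, 0.07 without PCDH_CX5461 replicate 2, 0.174 without ADAR-OE_cmc-na replicate 3 and 0.0843 without ADAR-OE_CX5461 replicate 2. The interferon median was 0.27 and 0.08 without PCDH_CX5461 replicates 1 and 3, 0.26 without ADAR-OE_cmc-na replicate 3, and 0.29 and 0.04 without ADAR-OE_CX5461 replicates 2 and 3. The NF-kB median was 0.47 without PCDH_cmc-na replicate 1 or ADAR-OE_CX5461 replicate 1 and 0.51 without ADAR-OE_cmc-na replicate 2, and the mesenchymal median 0.25 and 0.09 without PCDH_cmc-na replicates 1 and 2.

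Within ADAR-OE, the mean of the medians of the NF-kB and interferon lists with CX5461 was 0.36. With each of the 6 libraries of that comparison left out in turn it was lowest, 0.28, without ADAR-OE_CX5461 replicate 3, which argues against 1 library as the cause. It was highest, 0.57, without ADAR-OE_cmc-na replicate 2, so its size depends on that library. With GC and length trends removed it was 0.33, which argues against those trends. In the same comparison fibroblast markers were higher in 7 of 8 (median 0.47, camera adjusted p = 0.175), and skeletal muscle markers had a median of 2.84 (camera adjusted p = 0.464). MYH7 and MYH1 were higher adjusted over the muscle list alone and KRT14 over its own list. These genes were named after their values were seen. A response of tumour cells to the drug, a different share of host cells and a difference in handling between the groups stay open and were not tested.

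The median of the mitochondrial transcripts with CX5461 in ADAR-OE was 0.58, and 0.15 without ADAR-OE_cmc-na replicate 1 (camera adjusted p = 0.00323). That library was chosen after its mitochondrial share of 3.45%, against 6.25% and 7.85% in its group, had been seen, so leaving it out restates that share and is no test of a cause. No biological explanation was tested.

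The 252 genes called lower in ADAR-OE without drug had a median log2 fold change of -0.64. It was -0.55 without PCDH_cmc-na replicate 2, where 22 genes were called, 14 of them lower; since the genes were chosen with that library in the test, this decides nothing about its part. With GC and length trends removed it was -0.43, just under the size set for excluding those trends and over the size set for them as the cause. The genes were chosen by the fit that kept the trends, so their median can shrink for that reason too. The trends and the overexpression thus cannot be told apart for these genes. With CX5461, in libraries outside that contrast, the same genes had a median of -0.16, which likewise decides neither way on an effect shared by both arms.

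Other splits of the libraries were tested for each count of calls. For the average overexpression effect, 1 of 50 splits, the real one, gave 351 calls, and the highest of the others gave 29. For the average drug effect, 1 of 50 gave 18 and the highest of the others 7. The 50 splits were drawn from 200 possible ones, and both averages were chosen after the data had been seen. The splits therefore show only that no other drawn split reached the real count, and do not exclude chance. For the interaction the real count is 0, which all 50 splits reach by construction (the highest of the others was 2), so the splits say nothing about chance. For the comparisons of 3 libraries with 3, the 10 splits are too few: the real counts were 358 and 28 for ADAR-OE without drug and with CX5461, each reached by 1 split, and the highest of the others 3 and 17. For CX5461 in PCDH and in ADAR-OE the real count is 0, as is the highest of the others; all 10 splits reach it by construction, so they say nothing about chance.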

How the results depend on the processing

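The GC and length correction, the averages and the repeats of the list tests without each library were chosen only after the data had been seen. ADAR kept its call under every alternative run, with log2 fold changes of 1.92 to 2.14 without drug and 2.16 to 2.32 with CX5461 when 1 library was left out. All 88 named calls kept their direction in every setting, and 27 also kept the call (5 of 30 for ADAR-OE without drug, 6 of 15 with CX5461, 0 of 11 for the average of CX5461 and 16 of 32 for that of ADAR-OE); 1578 of 1980 alternative values were past the threshold. Below, counts are of called genes and the cause was not tested. Without the filter the counts were 479 for CX5461 in PCDH, 193 for CX5461 in ADAR-OE, 1054 and 150 for ADAR-OE without drug and with CX5461, 90 for the interaction, and 569 and 924 for the averages of CX5461 and ADAR-OE. With DESeq2 they were 273, 18, 931, 78, 0, 346 and 774 in that order. With log2(TPM + 1) they were 20 and 10 for ADAR-OE without drug and with CX5461, and 0 and 84 for the averages, and with log2(TPM + 0.1) 11, 18, 0 and 79. On the comparison's own groups alone ADAR-OE gave 26 without drug and 51 with CX5461; this setting does not exist for the interaction and the averages. With GC and length trends removed ADAR-OE without drug gave 55, and with limma-voom the average of CX5461 gave 2. Replicate numbers did not pair the libraries: of 18 same-number pairs 3 correlated above 0.1, and 5 of 12 libraries correlated best with their own number; with the number as a block ADAR-OE without drug gave 238 and the average of CX5461 gave 1. With 1 library left out the counts ran from 0 to 268 for CX5461 in PCDH, 0 to 117 in ADAR-OE, 22 to 766 for ADAR-OE without drug, 12 to 44 with CX5461, 0 to 0 for the interaction, 1 to 401 for the average of CX5461 and 111 to 527 for that of ADAR-OE. Called lists by camera ran from 2 to 4, 7 to 10, 3 to 6, 6 to 12, 3 to 6, 5 to 8 and 5 to 12 for CX5461 in PCDH and in ADAR-OE, ADAR-OE without and with CX5461, the interaction, and the averages of CX5461 and ADAR-OE. With an estimated correlation 0 lists were called in every comparison, and with fry 0, except 2 for the average of ADAR-OE. The Pearson r of the overexpression effects was 0.317 with the filter of 1 CPM, and with 1 library left out ran from 0.231 to 0.314; that of the drug effects ran from 0.044 to 0.205. Values of uncalled genes that changed sign, with their range when 1 library was left out, were CDKN1A for CX5461 in PCDH (-0.022 with trends removed; -0.056 without PCDH_cmc-na replicate 1 to 0.097, and -0.032 without PCDH_CX5461 replicate 3) and CXCL8 there (-0.154 without PCDH_cmc-na replicate 1 to 0.477). Others were IL7R in the interaction (-0.058 without ADAR-OE_CX5461 replicate 3 to 0.482) and NF1 in ADAR-OE with CX5461 (-0.557 to 0.051 without PCDH_CX5461 replicate 1). So were GDF15 in the average of CX5461 (-0.268 to 0.051 without PCDH_cmc-na replicate 1) and ADARB1 in the average of ADAR-OE (-0.0013 without ADAR-OE_cmc-na replicate 1 to 0.14). With 3 libraries per group, simulated 1.5-fold changes in genes with at least 5 CPM were not always called. The share called was 48% for ADAR-OE with CX5461 and 54% for CX5461 in PCDH. Changes of that size can therefore be missed.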

Other observations

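The markers of other tissues were counted as a check for host or neighbouring cells, and no test of their source was run. The build was human (hg38), to which host reads can align at conserved genes. A count of 0 or a low count therefore does not show that host cells were absent. The genes given were chosen after their values were seen. KRT14 had 14.9 CPM in ADAR-OE_CX5461 replicate 3, and MYH7 and MYH1 had 4.43 and 5.19 in ADAR-OE_CX5461 replicate 2. C1QA, C1QB, C1QC and TYROBP, genes of macrophages, had 0 counts over the 12 libraries, and PTPRC, the common leukocyte antigen, had 29. From the same list CD74, which carcinoma cells can also express, had 10055, CSF1R 541, CD14 288 and LYZ 76. DCN had 225 counts in all and COL1A1, a collagen of fibroblasts that tumour cells can also express, 7836.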
